A study of Homo sapiens and Mus musculus with 13 samples.

How the data were processed

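Messenger RNA libraries from mouse Th2 cells and from human T helper cells make up the series. Per the labels' protocols, total RNA was extracted from lysed cells, poly(A) RNA was selected with magnetic beads and libraries were made with a NEBNext Ultra RNA kit for Illumina sequencing. The deposited values are FPKM per gene and library, made by the authors from their reads. Per the submitters' processing notes, TopHat2 2.1.0, Cufflinks 2.2.1 and the genome builds mm10 and hg38 were used, with no role or order given. The gene annotation, the handling of reads that map to several places and the strand setting are not given in the sources used here, so genes with close paralogs, overlapping genes and antisense genes are uncertain.

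The mouse table held 25034 rows with 24483 distinct symbols. For the 283 symbols with several rows the row with the highest mean was kept. The 4 mouse value columns carry numbers that match 1 sample title each. The 9 value columns of the human table carry names that match no label, so the 9 human samples (3 groups, 3 donors per group) were not analysed here. The comparisons of human Th2 cells with naive T helper cells, of stimulated with resting human Th2 cells and of genes shared between the species were planned and are not given. No mouse gene annotation was used here, so no coordinates or gene lengths are given.

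FPKM divides by gene length and by the mapped fragments of a library, so a class of transcripts that takes a larger share of a library lowers all others, and the values of short features can be inflated and noisy. The table holds 1295 microRNA, snoRNA and other small RNA features, recognised by their symbols, and 331 of them passed the filter. Only the first letters of a symbol were used, so longer transcripts with such symbols may be among them. No counts or library totals were used, so the depth behind each value and a detection floor are unknown. None of the 20 housekeeping genes was listed at 0 in any library.

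Features with at least 1 FPKM in at least 2 of the 4 libraries were kept (11520), and log2(FPKM + 1) was compared between the 2 resting and 2 stimulated libraries with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend). The test was two-sided, with Benjamini-Hochberg adjustment over all features and a threshold of 0.05. The fit had 2 residual and 3.95 prior degrees of freedom. The test was chosen before the data were examined, as were the gene lists, the rule for named genes and the first set of alternatives listed below. No features had exactly equal values above 0 in both replicates of a group, so no library was treated as deposited a second time. The median SD between replicates was 0.0396 log2 in the resting group and 0.111 log2 in the stimulated group.

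Because the median feature moved by -0.42 log2, genes were said to rise or fall only if called in the same direction on the deposited FPKM and after median-of-ratios scaling. The size factors of that scaling were 1.19 and 1.21 for the resting libraries and 0.800 and 0.872 for the stimulated libraries. This convention was chosen after seeing the data. Fold differences in the text are ratios of deposited group means.

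Gene lists were tested with camera in limma with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 28 lists with tested members. The estimated correlation and fry were alternatives. The lists were the type 2 cytokine locus, type 2 cytokines, Th2 identity, Th1, Th17, regulatory T cell, follicular helper, naive and quiescence, immediate early, NF-kB and NFAT feedback, activation cytokines and chemokines, activation surface receptors, co-inhibitory receptors, cell cycle, glycolysis, cholesterol synthesis, ribosome biogenesis, interferon response, unfolded protein response, loop architecture, T cell receptor complex and proximal signalling, and housekeeping genes. Further lists held stress and RNA quality genes and markers of CD8 T and NK cells, B cells, myeloid cells, mast cells and basophils, dendritic cells, and erythroid cells and platelets. Of the list genes 4 were matched under an older symbol of the table.

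The named genes are all members of the locus list, the 10 largest rises and 10 largest falls among called genes, up to 4 called members of each list with the largest absolute change, and the genes of lineage regulators, among them Tbx21, Foxp3, Bcl6 and Gata3. Some genes that the rule names are not reported here. A gene qualified as a largest rise or fall if every library of one group lay above every library of the other, if the higher group had a mean of at least 5 FPKM and if it had a named symbol, which left out small RNA, histone, mitochondrial and numbered predicted genes.

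The test was checked on simulated data for this comparison, with 200 of 11520 genes changed. It recovered 20.6% of changes of 0.5 log2, 95.5% of 1 log2 and 97.0% of 2 log2, and 12 of its calls (7.84%) were false. Among 100 unchanged lists camera gave p under 0.05 for 4, and it found 20 of 20 raised lists. The simulated genes varied independently of each other. The check therefore cannot show whether camera's p-values hold for lists whose genes vary together. Its shares of recovered and false calls also do not carry over to the real fit, where 79.3% of features were called as deposited. The simulated changes held no shift of the median, so the rule of both scalings was not checked.

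Alternatives were a pseudocount of 0.1, no filter, a filter of 5 FPKM, median-of-ratios scaling, rescaling to TPM, limma without the trend, the replicate number as a block, and leaving out each library in turn. Added after seeing the data were rescaling without small RNA features, scaling to the housekeeping genes, leaving small RNA features out of the test, and summing the rows of a symbol. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.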

Results

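Messenger RNA was sequenced from mouse T helper 2 (Th2) cells, the CD4 T cell lineage that produces interleukins 4, 5 and 13, at rest and after stimulation. The cells came from the spleen of wild-type mice and were made into Th2 cells in culture, by the labels. The labels name 2 groups of 2 libraries each, both at 4 h. One group had no stimulus, and the other carries the label CD3 and CD28, which name a part of the T cell receptor complex and a co-stimulatory receptor. The values were FPKM, fragments scaled to transcript length and to the mapped fragments of a library, as deposited, and 11520 features that reached at least 1 FPKM in at least 2 libraries were tested. The FPKM of all features summed to 505631 and 495999 in the resting libraries and to 505621 and 591076 in the stimulated libraries. The sequencing depth is unknown, because the table holds no counts. Across genes, the log2 values of the replicates correlated with Pearson's r = 0.945 in the resting group and 0.956 in the stimulated group, against 0.735 between the group means. Without microRNA, snoRNA and other small RNA features the replicate values were 0.996 and 0.995. Genes are not independent replicates, so these correlations only describe the libraries. All values below are mean FPKM ± SD over 2 libraries per group unless stated otherwise.

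The series title points to the locus of Il4, Il13 and Il5, so the comparison of stimulated with resting Th2 cells addresses how these cytokine genes and the rest of the transcriptome differed between the states. After stimulation 9137 of the 11520 features differed by limma's moderated test with a Benjamini-Hochberg adjusted p under 0.05. As deposited, 2725 of them were higher and 6412 were lower, so that 29.8% of the calls were higher. The median feature had a log2 change of -0.42. With median-of-ratios scaling the calls numbered 9417, with 4691 higher and 4726 lower (49.8% higher), and the median change was 0.0095. "Rose" and "fell" are therefore used below only for genes called in the same direction in both scalings, which left 2718 that rose and 4726 that fell. Of these, 1811 rose and 1633 fell by at least 1 log2 relative to the median feature, and small RNA features made up 105 and 28 of them. The rule of both scalings is not symmetric. The falls number the same as the 4726 lower calls after scaling, while the rises are fewer than its 4691 higher calls. The size of an excess of falls over rises, also within a gene list, therefore depends in part on the shift of the median. Log2 changes below are on the log2(FPKM + 1) scale and relative to the median feature, which understates the change of low genes. Adjusted p-values are from the deposited values without that shift. The counts of list members called are also from the deposited values, where 79.3% of all features were called. A list with a share near that is not set apart by its count. With 2 libraries against 2, an exact permutation test of a single gene could not go below p = 0.333, so every call rests on the spread that limma pools across genes. Nothing in the labels says that replicates were separate cultures or animals, so the p-values measure the spread between these libraries, which may be technical.

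**Figure D1:**
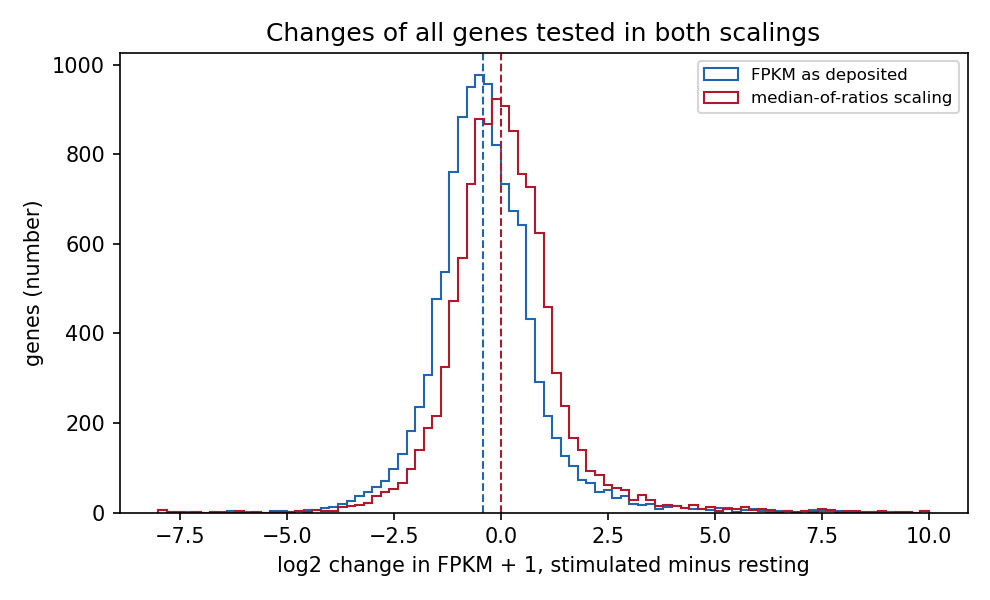
Number of genes (vertical axis) by log2 change in FPKM + 1 from resting to stimulated Th2 cells (horizontal axis) for the 11520 features tested, as deposited and after median-of-ratios scaling, with values beyond the ends placed in the outermost bins. Dashed lines mark the medians, -0.42 as deposited and 0.0095 after scaling.

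The 3 cytokine genes of the type 2 locus rose steeply after stimulation. Il4 went from 5.21 ± 0.629 FPKM at rest to 658 ± 62.0 FPKM, a 126-fold difference of the deposited means (relative log2 change 7.15, limma adjusted p = 8.61e-07). Il13 went from 3.70 ± 0.0969 to 1751 ± 136 FPKM, a 473-fold difference (8.96, limma adjusted p = 3.86e-07), and Il5 from 0.879 ± 0.00749 to 472 ± 37.3 FPKM, a 536-fold difference (8.39, limma adjusted p = 3.86e-07). The other members of the list were not called in both scalings. Rad50, which encodes a DNA repair protein and lies between Il13 and Il5, was at 16.5 ± 1.12 and 11.4 ± 0.477 FPKM (limma adjusted p = 0.00406 as deposited and 0.858 after median-of-ratios scaling). Kif3a, which encodes a kinesin motor subunit, was at 2.88 ± 0.296 and 2.37 ± 0.0162 FPKM (limma adjusted p = 0.0794). Irf1, an interferon-induced transcription factor gene, was at 36.8 ± 4.15 and 28.5 ± 1.85 FPKM (limma adjusted p = 0.0332 as deposited and 0.218 after scaling). At rest Il4 had the highest FPKM of the 3 cytokine genes, and after stimulation Il13 did. The ratio of Il13 to Il4 was 0.715 ± 0.0677 at rest and 2.66 ± 0.0437 after stimulation. The ratio of Il4 to Il5 was 5.93 ± 0.766 at rest and 1.40 ± 0.0210 after stimulation, and that of Il13 to Il5 was 4.21 ± 0.146 and 3.71 ± 0.00501. For each of the 3 ratios the groups did not overlap, and the two-sided exact permutation test on the log2(FPKM + 1) differences gave its smallest possible p of 0.333. On that scale the Il13 to Il5 difference was higher by 0.57 log2 after stimulation, opposite to the ratio, because the pseudocount weighs on the low resting Il5. The list as a whole was higher relative to other genes by camera (adjusted p = 0.0307), with adjusted p = 0.637 with an estimated correlation. That call was also lost with no filter (adjusted p = 0.0836), after rescaling without small RNA features (0.0634), with housekeeping scaling (0.0512) and without stimulated replicate 1 (0.0665) or 2 (0.0519). In the list 5 members were called over all genes and 5 adjusted over the list alone.

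**Figure D2:**
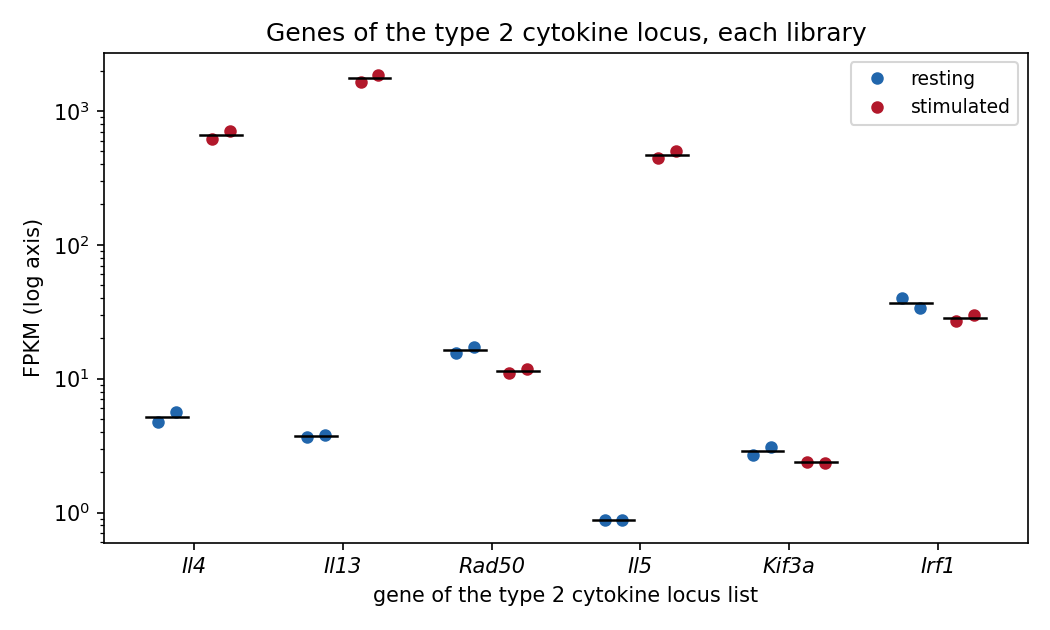
FPKM on a log axis (vertical) of the 6 genes of the type 2 cytokine locus list (horizontal) in each of the 2 resting and 2 stimulated mouse Th2 libraries, with a bar at the group mean. Il4, Il13 and Il5 went from 5.21, 3.70 and 0.879 to 658, 1751 and 472 FPKM, while Rad50, Kif3a and Irf1 were not called in both scalings.

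Cytokine and chemokine genes made up most of the largest rises. Ccl1, a chemokine gene, went from 2.12 ± 0.185 to 1782 ± 140 FPKM, with the largest relative log2 change of the genes eligible for naming (9.58). It was followed by Il3 (1.15 ± 0.0708 to 1074 ± 117 FPKM), a growth factor for haematopoietic cells, by Il13, and by Il24 (1.14 ± 0.0735 to 778 ± 22.3 FPKM). Il2, the T cell growth factor gene, went from 0.418 ± 0.129 to 448 ± 49.8 FPKM, and Csf2, which encodes GM-CSF, from 1.41 ± 0.107 to 528 ± 40.4 FPKM. The rest of the 10 were Il5, the activin subunit gene Inhba (0.776 ± 0.0982 to 443 ± 62.3 FPKM) and the chemokine genes Cxcl2 (0.272 ± 0.0633 to 267 ± 25.4 FPKM) and Ccl4 (2.36 ± 0.792 to 656 ± 78.6 FPKM). Limma adjusted p-values of the 10 lay between 3.86e-07 and 1.68e-06. All 10 tested members of the type 2 cytokine list rose, with 10 called over all genes and 10 adjusted over the list alone (camera adjusted p = 4.01e-11, and adjusted p = 0.637 with an estimated correlation). Of 27 tested activation cytokines and chemokines 24 rose and 2 fell, with 26 called over all genes and 26 adjusted over the list alone (camera adjusted p = 1.07e-14, and adjusted p = 0.637 with an estimated correlation). Il3, Csf2 and Il10 belong to both lists. The estimated correlations rest on 2 residual degrees of freedom, and with them none of the camera calls reported here held. They also take in any difference between replicates that most features share, so they do not by themselves show co-regulation. The median log2 difference of replicate 2 from replicate 1 was 0.130 in the stimulated group and 0.0271 in the resting group. Cxcl2 and Ccl4 have close paralogs, and how reads shared between paralogs were treated is not given in the sources used here.

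The genes with the largest falls included regulators of T cell quiescence. Cdc25b, a cell cycle phosphatase gene, went from 103 ± 3.64 to 1.12 ± 0.109 FPKM (relative log2 change -5.19). Pdcd4, a translation inhibitor gene, went from 132 ± 4.60 to 2.56 ± 0.599 FPKM, Ypel3 from 138 ± 2.87 to 3.07 ± 0.234 FPKM and Txnip, which encodes a thioredoxin-binding protein that limits glucose uptake, from 455 ± 12.9 to 13.4 ± 1.53 FPKM. Pik3ip1, an inhibitor of PI3 kinase, went from 47.1 ± 0.821 to 0.578 ± 0.0450 FPKM. The other 5 were Frmd8 (relative log2 change -4.33), Tcf7 (-4.29), Rnf125 (-4.27), Klf2 (-4.11) and Ctdsp2 (-4.01). Limma adjusted p-values of the 10 lay between 6.99e-07 and 1.96e-06. In the list of naive and quiescence genes 16 of 23 tested members fell and 4 rose, with 21 called over all genes and 21 adjusted over the list alone. Calls after median-of-ratios scaling alone were 16 lower and 5 higher, and the list was lower there too (camera adjusted p = 0.00980). Tcf7, a transcription factor gene of naive and memory T cells, went from 51.6 ± 1.93 to 1.01 ± 0.108 FPKM, and Klf2, which maintains quiescence and the expression of homing receptors, from 59.2 ± 0.958 to 1.60 ± 0.0441 FPKM. S1pr1, the receptor for egress from lymphoid organs, went from 55.5 ± 2.46 to 2.12 ± 0.370 FPKM, and Id3 from 24.2 ± 0.985 to 1.63 ± 0.460 FPKM. The list was lower by camera (adjusted p = 0.0307), with adjusted p = 0.752 with an estimated correlation, 0.060 after rescaling to TPM and 0.0837 without stimulated replicate 2.

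**Figure D3:**
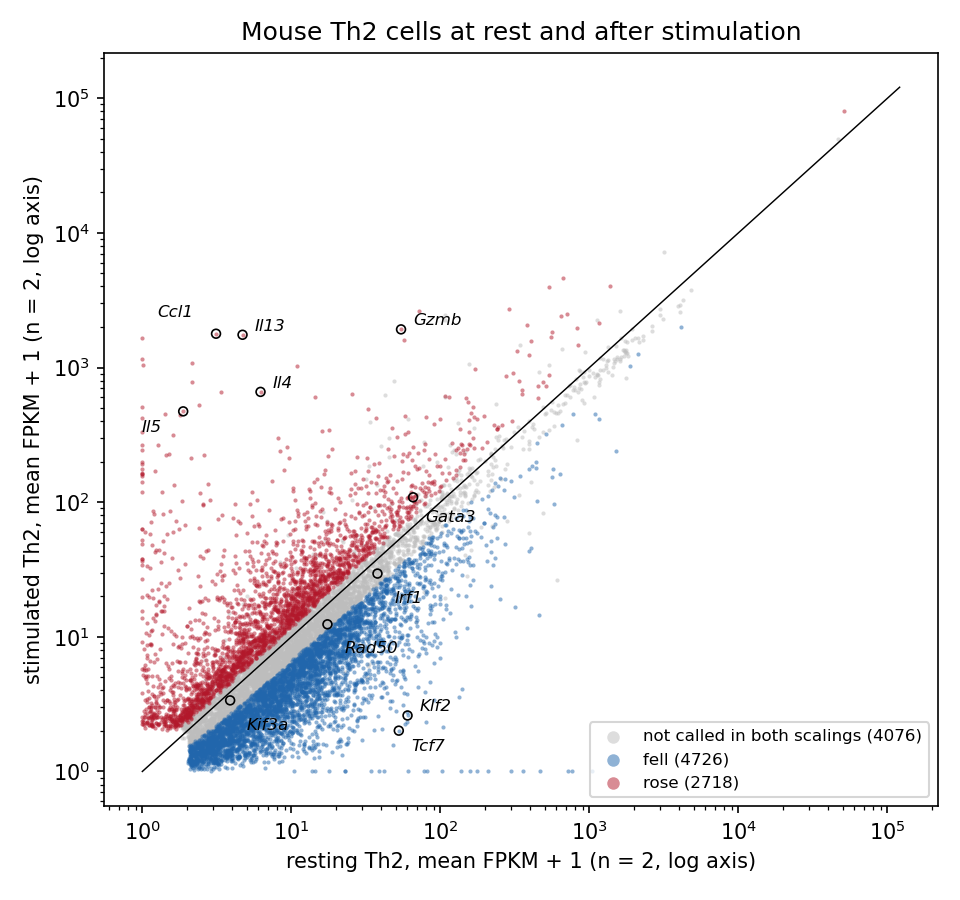
Mean FPKM + 1 of 2 resting libraries (horizontal log axis) against that of 2 stimulated libraries (vertical log axis) for 11520 features, with circles on named genes and a line of equality. In both scalings 2718 features rose and 4726 fell, and 4076 were not called in both; the points along the left and bottom edges, where the mean FPKM of one group is at or close to 0, include small RNA features.

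Early activation genes rose nearly throughout. Of 31 tested immediate early genes 30 rose and 1 fell, with 31 called over all genes and 31 adjusted over the list alone (camera adjusted p = 1.60e-17, and adjusted p = 0.637 with an estimated correlation). The largest rises in the list were those of Spry1, an inhibitor of growth factor signalling (0.354 ± 0.0758 to 118 ± 15.7 FPKM), the zinc finger gene Egr2 (0.622 ± 0.0382 to 134 ± 14.6 FPKM) and the orphan nuclear receptor genes Nr4a3 (0.187 ± 0.0473 to 84.6 ± 9.75 FPKM) and Nr4a1 (0.381 ± 0.0559 to 80.1 ± 6.49 FPKM). Of 24 tested genes of NF-kB and NFAT feedback 22 rose and 2 fell, with 24 called over all genes and 24 adjusted over the list alone (camera adjusted p = 3.34e-12, and adjusted p = 0.637 with an estimated correlation). Among them were Gadd45b (relative log2 change 5.67), Nfkbid (4.60), Relb (4.05) and Nfkbiz (3.94), of which Nfkbid and Nfkbiz encode nuclear regulators of NF-kB and Relb one of its subunits. Activation receptors rose in 13 of 15 tested genes, with 13 called over all genes and 13 adjusted over the list alone (camera adjusted p = 2.52e-09, and adjusted p = 0.637 with an estimated correlation). Tnfrsf9, which encodes the co-stimulatory receptor 4-1BB, went from 16.8 ± 0.396 to 342 ± 31.0 FPKM and Tnfrsf4, which encodes OX40, from 31.7 ± 0.0577 to 495 ± 22.7 FPKM. Cd69 and Cd83 rose by relative log2 changes of 4.43 and 3.95. Co-inhibitory receptors rose in 9 of 11 tested genes and fell in 2, with 11 called over all genes and 11 adjusted over the list alone (camera adjusted p = 0.000152, and adjusted p = 0.637 with an estimated correlation). Havcr2, which encodes TIM-3, went from 0.616 ± 0.0842 to 58.9 ± 6.80 FPKM, and Ctla4 from 46.6 ± 2.83 to 353 ± 39.1 FPKM. The ligand gene Cd274 rose (relative log2 change 2.76) and Cd101 fell (-1.56).

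Genes of the Th2 lineage rose in part. Of 17 tested Th2 identity genes 9 rose, none fell and 8 were not called in both scalings, with 12 called over all genes and 12 adjusted over the list alone (camera adjusted p = 0.000919, and adjusted p = 0.705 with an estimated correlation). With median-of-ratios scaling alone 15 were called higher and 0 lower. Gata3, the lineage-defining transcription factor gene, went from 64.6 ± 2.50 to 108 ± 10.1 FPKM (relative log2 change 1.15, limma adjusted p = 0.00145). The largest rises were those of Stat5a (15.6 ± 0.0904 to 162 ± 12.5 FPKM), Ptgs2 (0.0194 ± 0.0127 to 4.66 ± 0.885 FPKM), the chemokine receptor gene Ccr8 (30.6 ± 2.34 to 131 ± 8.54 FPKM) and Bhlhe41 (1.23 ± 0.0184 to 3.85 ± 0.494 FPKM).

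Regulators and effector genes of other helper lineages also rose, most of them from low levels. Ifng, Fasl and Il21 are also on the list of activation cytokines and chemokines, so the lineage lists are not separate from it. Tbx21, which encodes the Th1 regulator T-bet, went from 0.391 ± 0.0310 to 15.8 ± 0.945 FPKM (relative log2 change 4.02, limma adjusted p = 1.68e-06). Bcl6, the regulator gene of follicular helper cells, went from 3.65 ± 0.0885 to 5.33 ± 0.239 FPKM (0.86, limma adjusted p = 0.00329, and 0.0642 without resting replicate 2). Foxp3, the regulatory T cell regulator gene, stayed below the filter at 0.406 ± 0.0585 and 0.185 ± 0.0194 FPKM and was not tested. In the Th1 list 8 of 14 tested genes rose and 5 fell, with 13 called over all genes and 13 adjusted over the list alone. Ifng went from 0.238 ± 0.132 to 16.2 ± 1.03 FPKM, and Fasl, which encodes a death receptor ligand, from 2.54 ± 0.216 to 27.9 ± 3.63 FPKM. Stat4, which transmits interleukin 12 signals, fell from 16.9 ± 0.627 to 1.61 ± 0.0303 FPKM. The Th1 list was higher by camera as deposited (adjusted p = 0.0232), with adjusted p = 0.281 after median-of-ratios scaling and adjusted p = 0.674 with an estimated correlation. That call was also lost with no filter (adjusted p = 0.110), with a filter of 5 FPKM (0.250), after rescaling without small RNA features (0.102), with housekeeping scaling (0.180) and without stimulated replicate 1 (0.0565). In the Th17 list 7 of 8 tested genes rose and 1 fell, with 8 called over all genes and 8 adjusted over the list alone (camera adjusted p = 4.85e-05, and adjusted p = 0.637 with an estimated correlation). Il17f went from 0.122 ± 0.108 to 31.6 ± 4.86 FPKM, Il17a was listed at 0 in both resting libraries and at 8.21 ± 1.91 FPKM after stimulation, and Ahr, a ligand-activated transcription factor gene, went from 0.478 ± 0.0172 to 10.6 ± 1.28 FPKM.

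In the list of regulatory T cell genes 7 of 11 tested members rose and 3 fell, with 10 called over all genes and 10 adjusted over the list alone. Il2ra, the interleukin 2 receptor gene (56.6 ± 2.29 to 439 ± 25.5 FPKM), and Ctla4 rose, both of which are also on the activation or co-inhibitory lists. Itgae (relative log2 change -1.74) and Lrrc32 (-1.58) fell. The list was higher by camera as deposited (adjusted p = 0.0143), with adjusted p = 0.0774 after median-of-ratios scaling, 0.0747 with no filter, 0.147 and 0.136 without resting replicate 1 and 2, and adjusted p = 0.708 with an estimated correlation. In the list of follicular helper genes 6 of 9 tested members rose and 2 fell, with 8 called over all genes and 8 adjusted over the list alone (camera adjusted p = 0.00471, adjusted p = 0.147 with no filter, and adjusted p = 0.637 with an estimated correlation). Il21, a cytokine gene, went from 0.522 ± 0.0420 to 85.3 ± 8.07 FPKM, Pou2af1 from 0.518 ± 0.0943 to 24.1 ± 3.32 FPKM and Cd200 from 1.56 ± 0.0113 to 37.3 ± 2.61 FPKM, while Slamf6 fell (-1.78).

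Genes for making ribosomes rose and cell cycle genes fell. Of 33 tested ribosome biogenesis genes 32 rose and 1 fell, with 33 called over all genes and 33 adjusted over the list alone (camera adjusted p = 2.32e-16, and adjusted p = 0.637 with an estimated correlation). Rrp9 went from 9.92 ± 0.340 to 87.1 ± 8.93 FPKM, Ppan from 12.3 ± 1.24 to 106 ± 8.82 FPKM, Rrp12 from 4.43 ± 0.0217 to 37.1 ± 3.86 FPKM and Rrs1 from 9.56 ± 0.410 to 62.2 ± 7.16 FPKM. Of 39 tested cell cycle genes 29 fell and 3 rose, with 33 called over all genes and 33 adjusted over the list alone (camera adjusted p = 0.00471, and adjusted p = 0.637 with an estimated correlation). Calls after median-of-ratios scaling alone were 29 lower and 7 higher, and the list was lower there too (camera adjusted p = 0.00196). The proliferation marker gene Mki67 went from 40.3 ± 1.69 to 3.52 ± 0.446 FPKM, the topoisomerase gene Top2a from 37.2 ± 2.66 to 4.78 ± 0.746 FPKM, and the mitotic cyclin genes Ccnb2 and Ccnb1 from 19.3 ± 0.832 to 1.19 ± 0.188 FPKM and from 15.3 ± 0.577 to 2.02 ± 0.352 FPKM.

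Metabolic lists moved in both directions. In glycolysis 6 of 19 tested genes rose and 5 fell (camera adjusted p = 0.551), with 15 called over all genes and 15 adjusted over the list alone. Median-of-ratios scaling alone gave 10 higher and 5 lower calls. Hk2, a hexokinase gene, rose from 2.15 ± 0.163 to 28.4 ± 2.95 FPKM, whereas Pdk1, which encodes an inhibitory kinase of pyruvate dehydrogenase (relative log2 change -2.64), the glucose transporter gene Slc2a3 (-1.43) and Pfkm (-1.12) fell. In cholesterol synthesis 8 of 23 tested genes rose and 10 fell (camera adjusted p = 0.322), with 19 called over all genes and 19 adjusted over the list alone. Here that scaling alone gave 12 higher and 10 lower calls. Hsd17b7 (3.48), Idi1 (2.21) and Cyp51 (2.09) rose, and Srebf2, the regulator gene of the pathway, fell (-1.40).

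In the unfolded protein response list 15 of 25 tested genes rose and 2 fell, with 20 called over all genes and 20 adjusted over the list alone (camera adjusted p = 0.000340, and adjusted p = 0.708 with an estimated correlation). The chaperone gene Hspa5 went from 78.9 ± 2.18 to 426 ± 48.7 FPKM, and Asns (4.14 ± 0.0457 to 15.4 ± 0.0494 FPKM), Chac1 (relative log2 change 1.75) and Calr (1.73) also rose. In the interferon response list 3 of 18 tested genes rose and 10 fell (camera adjusted p = 0.379), with 15 called over all genes and 15 adjusted over the list alone. Calls after median-of-ratios scaling alone were 4 higher and 10 lower (camera adjusted p = 0.485). Ifih1, a sensor of viral RNA, rose (2.78), and Cmpk2 (-1.70) and Ifit2 (-1.48) fell.

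Of 23 tested genes of loop architecture, which encode CTCF, cohesin and its regulators and other proteins of chromatin loops, 14 fell and 1 rose, with 18 called over all genes and 18 adjusted over the list alone. With median-of-ratios scaling alone 14 were called lower and 7 higher. The list did not pass camera's threshold (adjusted p = 0.0619 as deposited, adjusted p = 0.20 after median-of-ratios scaling and adjusted p = 0.752 with an estimated correlation). It was called lower with no filter (0.000627), after rescaling to TPM (0.0183) and without stimulated replicate 2 (0.0240). Ldb1, which encodes a factor that bridges enhancers and promoters, went from 108 ± 0.146 to 15.2 ± 1.72 FPKM. Top2b (relative log2 change -1.62), the cohesin deacetylase gene Hdac8 (-1.37) and the cohesin subunit gene Stag2 (-1.27) fell too. Of 27 tested genes of the T cell receptor complex and its proximal signalling 8 rose and 13 fell (camera adjusted p = 0.892), with 23 called over all genes and 23 adjusted over the list alone. Median-of-ratios scaling alone gave 13 higher and 13 lower calls. The median of the list relative to the median feature was -0.0970 and its mean -0.122, while camera's direction was up. Grap2 (-2.08), Plcg1 (-1.97) and Cd4 (-1.53) were among those that fell.

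**Figure D4:**
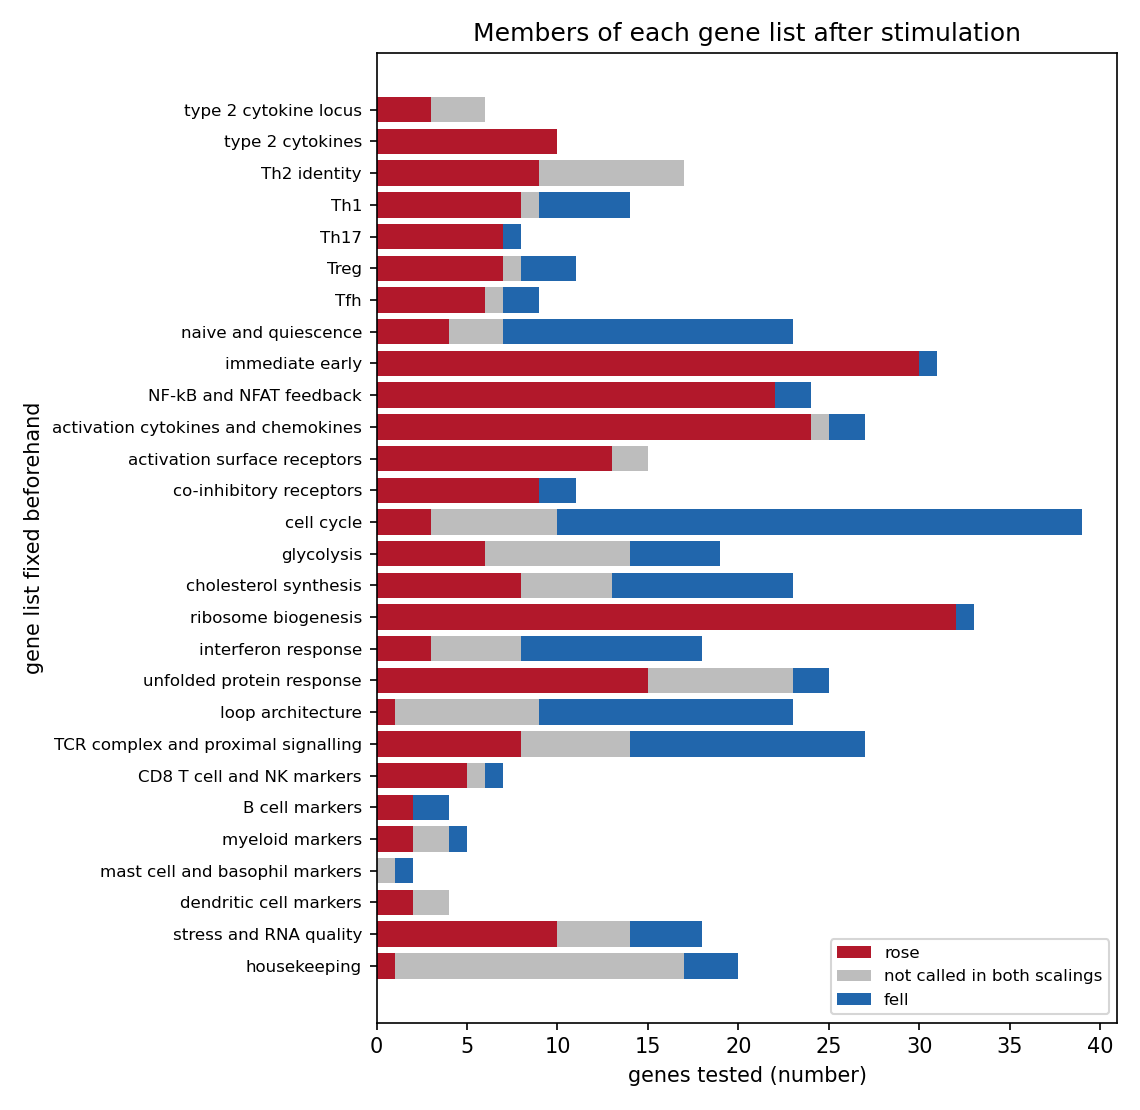
Number of tested genes (horizontal axis) of each of 28 gene lists fixed beforehand (vertical axis) that rose, fell or were not called in both scalings in stimulated against resting mouse Th2 cells. For ribosome biogenesis 32 of 33 rose, for immediate early genes 30 of 31 rose and for the cell cycle 29 of 39 fell.

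Markers of other cell types were mostly low or below the filter. Among markers of CD8 T cells and NK cells 5 of 7 tested genes rose and 1 fell, with 7 called over all genes and 7 adjusted over the list alone (camera adjusted p = 0.00858, and adjusted p = 0.637 with an estimated correlation). The members that rose included cytotoxic effector genes, namely Gzmb, which encodes granzyme B (53.5 ± 0.238 to 1920 ± 228 FPKM), Nkg7 (2.30 ± 0.00709 to 29.8 ± 0.821 FPKM) and the perforin gene Prf1 (0.439 ± 0.0270 to 5.37 ± 0.387 FPKM), while Klrd1 fell (1.71 ± 0.328 to 0.476 ± 0.0930 FPKM). Of 4 tested B cell markers 2 rose and 2 fell (camera adjusted p = 0.598), with 4 called over all genes and 4 adjusted over the list alone, and all group means were under 4 FPKM. They were Cd79b (relative log2 change -1.07), Cd72 (-0.15), Ebf1 (1.56) and Fcer2a (0.92), the last of which was not called after rescaling to TPM (limma adjusted p = 0.150) or with no filter (0.0865). Of 5 tested myeloid markers 2 rose and 1 fell (camera adjusted p = 0.420), with 4 called over all genes and 4 adjusted over the list alone. Clec7a (2.83) and Csf3r (0.92, limma adjusted p = 0.190 after rescaling to TPM, 0.121 with no filter and 0.0634 after rescaling without small RNA features) rose and Ctss (-0.60) fell, and Cst3 was at 146 ± 3.47 and 111 ± 5.37 FPKM without a call in both scalings. Of the 2 tested mast cell and basophil markers Cpa3 fell (-0.41) and Il3ra was not called in both scalings (camera adjusted p = 0.507), with 2 called over all genes and 2 adjusted over the list alone. Of 4 tested dendritic cell markers Irf8 (2.59) and Batf3 (1.65), which activated T cells also express, rose, while Xcr1 was at 8.73 ± 0.235 and 5.80 ± 1.11 FPKM without a call in both scalings (camera adjusted p = 0.0674), with 3 called over all genes and 3 adjusted over the list alone. No erythroid or platelet marker passed the filter.

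The list of stress and RNA quality genes was higher by camera (adjusted p = 0.0158), with adjusted p = 0.752 with an estimated correlation. That call was also lost with no filter (adjusted p = 0.110), with a filter of 5 FPKM (0.163), without small RNA features in the test (0.189) and without resting replicate 1 (0.190) or 2 (0.183). Of its 18 tested genes 10 rose and 4 fell, with 15 called over all genes and 15 adjusted over the list alone. The chaperone genes Hspd1 (relative log2 change 2.73) and Hsph1 (2.28) rose, and Txnip (-4.57) and the pro-apoptotic gene Bbc3 (-3.12) fell. Of 20 housekeeping genes 16 were not called in both scalings, 1 rose and 3 fell (camera adjusted p = 0.598), with 13 called over all genes and 10 adjusted over the list alone. With median-of-ratios scaling alone 11 were called higher and 3 lower. Actb (-0.44), Sdha (-0.41) and Pgk1 (-0.37) fell, and Polr2a was not called in both scalings. The list's median was 0.0716 relative to the median feature, while camera's direction was down. Small RNA features took 33.9% and 31.6% of the summed FPKM in the resting libraries and 43.6% and 47.1% in the stimulated libraries. Much of this came from 2 features. Mir6236 alone took 10.6% and 10.1% at rest and 13.2% and 16.3% after stimulation. Mir6240 took 10.3% and 8.56% at rest and 8.58% and 9.86% after stimulation.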

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

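Rescaling without small RNA features, scaling to the housekeeping genes, leaving out small RNA features, summing the entries of a symbol and the counts called in both scalings were chosen after seeing the data. Scaling decided the split of calls: with median-of-ratios scaling 4691 features were higher, 1866 by at least 1 log2, and 1706 were lower by at least 1 log2. The median log2 change was then 0.0095, by that scaling's construction, against -0.0095 with no filter, -0.565 after rescaling to TPM, -0.309 after rescaling without small RNA features and -0.135 after scaling to the housekeeping genes. With no filter 1058 features rose and 2941 fell in both scalings by at least 1 log2 relative to the median, because that median then lay close to 0. The other counts over all features stayed within 1.5 times their value, as did 572 list counts but not 40, and leaving out each library in turn gave 7852 to 9855 calls, the lone library being assumed to vary like the others. Among 119 tested named genes, Kif3a (0.17), Irf1 (0.147), Cst3 (0.124) and Il3ra (0.134) changed sign in log2 with median-of-ratios scaling and were not called there, and Kif3a also did with housekeeping scaling (0.049). The other gene values kept their direction, with 1737 on the same side of the threshold and 26 no longer past it. The list tests gave 404 values on the same side, 41 weaker, 8 stronger and 21 of opposite direction; of the latter lists only the stress list was called on the deposited values. With no filter these were glycolysis (adjusted p = 0.797), the T cell receptor list (0.346) and mast cell and basophil markers (0.797), and with a filter of 5 FPKM myeloid markers (0.461). With median-of-ratios scaling they were the T cell receptor list (0.987), B cell markers (0.987) and housekeeping genes (0.0945), and with TPM the T cell receptor list (0.981). Housekeeping scaling turned the housekeeping list (0.620), and leaving out small RNA features turned the T cell receptor list (0.665) and the housekeeping list (0.919). Leaving out 1 library turned these lists in some of the 4 runs, and over all 4 their adjusted p ranged from 0.809 to 0.947 and from 0.233 to 0.695. With fry, which does not compare a list with other genes, the directions of the T cell receptor list (adjusted p = 0.0388), B cell markers (0.00453), glycolysis (0.0732), cholesterol synthesis (0.695) and the stress list (0.998) were opposite; the cause of these turns was not tested. With the estimated correlation all 18 camera calls were lost. The other 23 lost list calls belong to 6 lists, namely the type 2 cytokine locus (5), Th1 (6), regulatory T cell (4), follicular helper (1), naive and quiescence (2) and stress lists (5). The replicate block gave 9488 calls, 2951 higher and 6537 lower. It was kept as an alternative because the labels do not say that replicate numbers pair cultures. The deviations of same-numbered libraries had a correlation of 0.0290 across all features tested, noisy small RNA features included. That value cannot decide whether the numbers pair cultures. The planned human and cross-species alternatives were not run. Without counts, depth limits cannot be given.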

Other observations

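The genes of the next 2 paragraphs, and the tests in the 3 that follow, were chosen after their values were seen. Among features without small RNA, 47 of 73 tested genes that the deposited table calls cytokines rose by at least 1 log2 relative to the median feature (64.4%), against 15.2% of all 11189 features (Fisher's exact test, Benjamini-Hochberg adjusted p = 2.70e-20 over 16 types). Of the other types, those with a larger share than all features and an adjusted p under 0.05 were growth factors with 15 of 35 (42.9%, adjusted p = 0.000330), transmembrane receptors with 41 of 147 (27.9%, adjusted p = 0.000330) and transcription regulators with 185 of 916 (20.2%, adjusted p = 0.000229). The test by type was not planned. It takes genes as independent, so its p-values only describe the shares. Estimated inter-gene correlations were 0.60 in the type 2 cytokine list and 0.63 in the list of activation cytokines and chemokines. They were 0.90 in the housekeeping list and 0.94 in the T cell receptor list but 0.13 in the cell cycle list. High values are thus not particular to cytokine genes. The growth factor gene Areg, which encodes amphiregulin, went from 0.219 ± 0.0297 to 169 ± 7.26 FPKM and Hbegf from 0.233 to 43.3 FPKM. Penk, which encodes proenkephalin, the precursor of opioid peptides, had the highest mean FPKM after stimulation of the genes that rose by at least 2 log2, small RNA left out, at 2622 ± 242 FPKM against 70.4 ± 3.18 at rest. Crabp2, which encodes a retinoic acid binding protein, went from 0.612 to 313 FPKM, and Olr1, a scavenger receptor gene, from 0.432 to 224 FPKM. Tnfsf11, which encodes RANKL, went from 13.5 ± 0.780 to 605 ± 73.3 FPKM, and Il10 from 9.88 ± 0.979 to 1027 ± 73.6 FPKM.

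Other types held genes that moved both ways. Of 91 tested genes that the table calls G-protein coupled receptors, 18 rose and 22 fell by at least 1 log2 relative to the median feature. The chemokine receptor genes Cxcr4 (30.7 to 4.30 FPKM) and Ccr2 (54.5 to 9.05 FPKM) and the lipid receptor gene S1pr4 (90.0 to 5.36 FPKM) fell, while Ccr8 and Gpr183 (3.05 to 11.2 FPKM) rose. Of the 147 transmembrane receptors 28 fell by that much, among them Ifngr1 (52.4 to 4.58 FPKM), Il7r (390 to 42.1 FPKM), Il9r (11.1 to 0.608 FPKM) and the integrin gene Itga4 (46.2 to 3.79 FPKM), while Il1r2 (14.8 to 76.2 FPKM) was among the 41 that rose. Of 82 translation regulators 20 rose and 4 fell by that much. Eif5a (164 to 512 FPKM) and Eif4a1 (159 to 460 FPKM) rose, and the translation repressor gene Eif4ebp2 fell (75.8 to 18.7 FPKM).

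The median feature was lower after stimulation by 0.42 log2. A larger share of small RNA features does not account for the whole shift. Rescaling the libraries over all features (TPM) gave a median of -0.565, and rescaling over all features but small RNA left the median at -0.309. Removing also the 115 genes among the 100 most abundant of either group left it at -0.321, which argues against a few abundant genes as the whole cause. Against the housekeeping genes the median was -0.135, and 2 standard errors of that list span -0.317 to 0.0474, so a fall of most genes against housekeeping genes and no such fall cannot be told apart. The libraries' total RNA per cell was not measured here, so a change in RNA content of the stimulated cells stays open.

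Small RNA features were 80 of the 187 features with a change of at least 4 log2 relative to the median (42.8%), although they were 2.87% of those tested. On the deposited values 158 of the 331 were called, a smaller share than the 9137 of all 11520 features. The median absolute difference of small RNA features between replicates was 0.962 log2, against 0.110 log2 for other features matched on mean level. In the 2 other splits of the 4 libraries into pairs 32 and 26 small RNA features differed by at least 4 log2, so the count in the real split was 2.5 times the higher of these. This argues against noise that is independent between libraries as the whole cause of the 80 changes, although it may account for part of them. Deviations shared by the 2 libraries of a group, in how short RNA passed the poly(A) selection for example, and a change of the small RNAs themselves were not tested and stay open.

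Genes of other lineages, among them Gzmb, Ifng, Tbx21 and Il17f, rose in the Th2 cultures. A larger share of CD8 T cells or NK cells in the stimulated libraries would raise Cd8a, Cd8b1, Klrd1, Tyrobp, Ncr1 and Klrk1 along with Gzmb, if their mRNA per cell stayed the same. The summed FPKM of these 6 genes was 7.52 ± 0.529 at rest and 5.59 ± 0.604 after stimulation, and after median-of-ratios scaling it differed by 1.07-fold, against 35.9-fold as deposited and 51.3-fold after scaling for Gzmb. These 6 genes argue against a larger share of such cells with unchanged mRNA per cell as the source of the Gzmb rise. Nkg7 (2.30 to 29.8 FPKM) and Prf1 (0.439 to 5.37 FPKM), on the same marker list but left out of the sum, rose with Gzmb. The result therefore depends on the markers chosen. Marker mRNA per cell was not measured, and Cd4 fell from 140 ± 3.86 to 35.6 ± 2.62 FPKM in these cultures. A larger share of CD8 T or NK cells with less marker mRNA per cell therefore stays open. So does a constant small share of CD8 T or NK cells that induced Gzmb on stimulation. Th1 cells already present at rest stay open, since Tbx21 was at 0.391 FPKM at rest, which a small share of Th1 cells or a low level in many cells could give, and bulk libraries cannot separate them from induction by the stimulus.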
